A study of Homo sapiens with 6 samples.

How the data were processed

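Total RNA of MCF-7 cells, a breast cancer cell line, and of MCF-7/ADM cells, a line labelled as chemoresistant and commonly named for adriamycin (doxorubicin), was measured on 6 single-colour Agilent microarrays, 3 per line. Labelled cRNA was made from 0.2 ug of RNA per array with Cy3, per the labels' protocols. The labels do not say whether the 3 samples of a line came from separate cultures, so p-values measure the spread between these samples, which may be technical.

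Each array held 178769 spots, of which 173795 were not controls, and these carried 111019 probes of 60 nt with 111006 distinct sequences. Probe identifiers formed 2 families. In the catalogue family (identifiers beginning with A) were 32776 probes, 31276 of them spotted 2 times and 1500 spotted 10 times. In the custom family (identifiers beginning with CUST) were 78243 probes, 76243 of them spotted 1 time and 2000 spotted 10 times. The families are named here by identifier only, and neither is taken as a class of transcript.

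The deposited scanner files give a linear intensity per spot, per the file headers. Agilent Feature Extraction 10.7.1.1 subtracted the background, detrended the spots spatially and multiplicatively within each array and replaced the signal of dim spots by surrogates, per the file headers, with no scaling between arrays. Such surrogates compress differences between dim probes. The headers name hg19 as the genome build of the design, but every probe is listed as unmapped, so no position is given. The authors' deposited value table holds 1 log2 value per probe and array. All 6 of its columns shared a median of 5.06, a minimum of 2.16 and a maximum of 19.2. Its rows matched all 111019 probes, and its columns correlated with the log2 scanner intensity at r = 0.996 to 0.999 across probes. The authors' log2 values were therefore treated as quantile normalised between arrays; the tool that did this is not given in the sources used here.

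In the scanner files the gene name column repeats the probe identifier, and 0 probes carried a gene name or a position. The reference table used here lists genes without probe sequences. Results planned per gene, namely protein-coding genes, long non-coding RNAs, fixed gene lists, ABCB1, antisense RNAs with their host genes and neighbouring genes, were therefore not analysed here. No gene was named from an identifier or by recognising a sequence. The planned rule for named genes took the highest and lowest changes among called features well above background on all 6 arrays. It was applied to probes, and 2 probes that rose and 2 that fell are printed. The human control probes, which the files do name, were added after the files were seen.

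For the main comparison, control spots and spots marked as outliers were left out, the spots of a probe were averaged on the log2 scale, and the 75th percentile of each array was subtracted. A probe was kept when at least as many of its spots were well above background as were not, on all 3 arrays of at least 1 line. For a probe spotted 2 times, 1 such spot per array was enough. The lines were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with line as the only factor and Benjamini-Hochberg adjustment over the probes kept. A probe was called when its adjusted p was under 0.05 and it differed at least 2-fold. This design, its thresholds and most alternatives were fixed before the data were examined. The exceptions are the control probes, the split into families, the pairs of overlapping probes and the comparison within the slide that held both lines.

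For probes well above background on all 3 arrays of 1 line and no array of the other, a lower bound of the fold was computed. It set the mean of the bright line against the mean, over the arrays of the dim line, of the higher of 2 values: the probe's own signal and the lowest signal of any probe well above background. Human control probes were fitted together with the probes kept, and their p-values adjusted with them.

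Overlapping probes were found by sequence in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. A pair was same-strand when the end of one sequence matched the start of the other over at least 20 nt, and reverse-complement when it matched the start of the other's reverse complement. Reverse-complement pairs thus overlap at the ends of both sequences, and pairs overlapping only at their starts were not searched for. Correlations across pairs were tested with 100000 permutations, two-sided, in scipy 1.17.1; Fisher's exact test compared shares between families. Intervals of differences in shares are normal approximations at 95%, and they treat probes as independent, although probes of the same transcript are not.

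The limma step was checked on simulated data with 200 of 55895 probes changed and 3 arrays per line. It recovered 52% of the probes changed 2-fold and 85% of those changed 4-fold, with 6 false calls. Recovery was counted by an adjusted p under 0.05 alone, with no minimum fold. A far smaller share of probes was changed than was called in the data, so recovery there may differ. The simulated arrays varied independently, with no difference between slides, so the few false calls say nothing of calls that slides may cause. Under the full rule, many probes changed exactly 2-fold would also fall under the fold threshold by chance. The overlap search, tested on simulated data, recovered 200 of 200 pairs of each kind. All simulated reverse-complement pairs overlapped at their ends, so this check says nothing of pairs overlapping at their starts.

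Alternatives comprised quantile normalisation, median centring, normexp background correction with an offset of 50 followed by quantile normalisation, the authors' value table, other filters on dim probes, other fold thresholds, treat, the replicate number or the slide as a block, a variance trend with robust estimation, and leaving out each array in turn. The arrays lay on 2 slides: the first held the 3 MCF-7 arrays and MCF-7/ADM replicate 1, and the other held MCF-7/ADM replicates 2 and 3. Each slide had its own scan, so slide and scan cannot be separated. The comparison within the first slide was added after seeing the data; it and the slide as a block both rest on a single MCF-7/ADM array. With 3 arrays per line, the number of arrays limits the precision.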

Results

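RNA of MCF-7 breast cancer cells and of the chemoresistant MCF-7/ADM line was profiled on 3 arrays per line, in a series whose title sets out to describe long non-coding RNA expression in chemoresistant cells. The design holds a single comparison, MCF-7/ADM against MCF-7. No spot was saturated on any of the 6 arrays. On the MCF-7 arrays 48.9%, 51.6% and 51.3% of non-control spots were well above background. On the MCF-7/ADM arrays the shares were 48.1% for replicate 1 and 66.4% for both replicates 2 and 3, which were hybridised on a second slide. Negative controls lay 4.57 to 4.94 log2 units below the 75th percentile of the array on the first slide, and 6.79 and 6.74 units below it on the other.

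The lines separated far more than their replicates did. Across the 45411 probes above background on all 6 arrays, log2 levels correlated at r = 0.991 to 0.995 between MCF-7 arrays and at 0.897 to 0.902 between the lines. The correlation was 0.997 between MCF-7/ADM replicates 2 and 3 and 0.980 between either of them and replicate 1. These correlations are across probes, which are not independent replicates. The first principal component held 86.8% of the variance and parted the lines. The second held 7.79% and set MCF-7/ADM replicate 1, at a score of -0.29 log2 units (root mean square per probe), apart from replicates 2 and 3, at 0.14 and 0.13. Replicate arrays of a line differed by 2.15 to 4.04 times the error between spots, so no array repeated the values of another. Spot error alone does not tell whether arrays of a line shared an RNA sample.

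**Figure D1:**
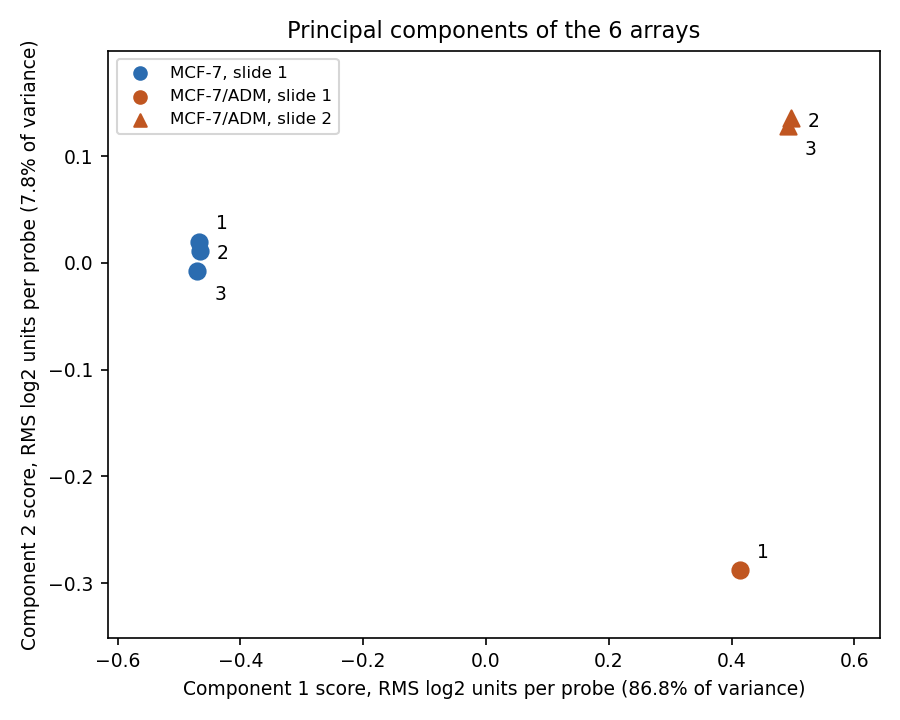
Scores of the 6 arrays on the first (horizontal) and second (vertical) principal components of 45411 probes, in log2 units as a root mean square per probe, each point an array numbered by replicate, coloured by line and shaped by slide. The first component, 86.8% of the variance, separates the lines, and the second, 7.79%, sets MCF-7/ADM replicate 1 at -0.29.

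RNA levels differed widely between the lines, in both directions. Of the 55895 probes tested, 15310 (27.4%) differed at least 2-fold with limma and Benjamini-Hochberg adjustment, 7842 of them higher and 7468 lower in MCF-7/ADM. Of the called probes, 2688 of those higher and 676 of those lower were above background on no array of the other line, and these enter the following sizes at the lower bound of their fold. At least 8-fold changes were then seen in 1362 probes that rose and 1139 that fell, and at least 64-fold changes in 132 and 142. The lowest signal well above background, which enters the bound, was -3.92 to -3.73 on the MCF-7 arrays. On the MCF-7/ADM arrays it was -3.53 for replicate 1 and -5.71 and -5.72 for replicates 2 and 3. Bounds can thus be larger for probes that fell, and their sizes are not comparable between directions. As fitted, the 64-fold counts were 221 and 188. Of the called probes, 8911 were well above background on all 6 arrays, 4292 of them higher and 4619 lower. The median change of the called probes was 1.74 log2 units among those higher and 1.62 among those lower, in absolute size (1.84 and 1.62 as fitted), against a median standard error of 0.12. Without regard to fold or adjustment, limma gave an unadjusted p under 0.05 for 36395 probes. The 3 arrays of one line did not overlap the 3 of the other for 37899 of the 55895 probes. Chance gives 10% among unselected probes. The filter, however, also kept probes above background in 1 line only, for which arrays of the lines seldom overlap, so 10% is no exact reference here. With the slide as a block, 15627 probes were called, of which 13801 were also called without it. The second slide held only MCF-7/ADM, so this fit takes the difference between the lines from the first slide and its single MCF-7/ADM array. The first slide fitted alone gives the same differences and is no separate check. It called 15307 probes, with the single array assumed to vary as MCF-7 does.

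**Figure D2:**
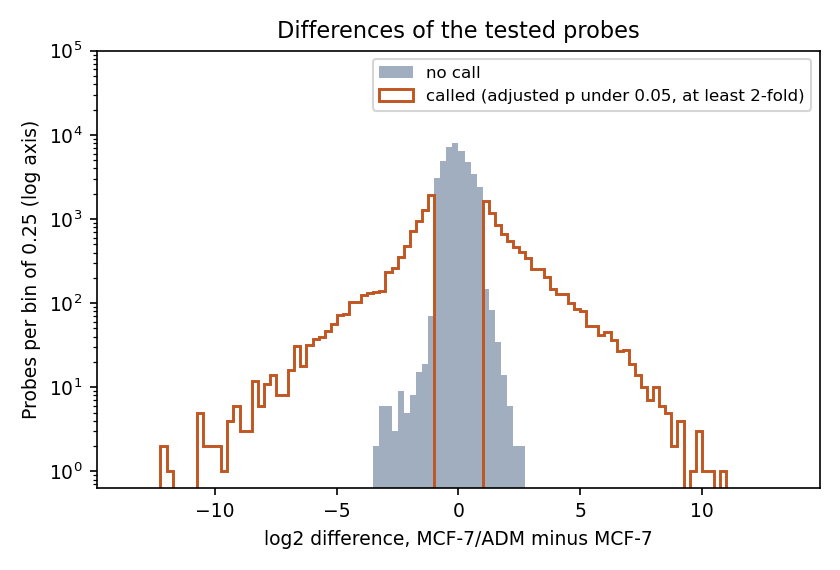
Histogram of the log2 difference between MCF-7/ADM and MCF-7 (horizontal) over 55895 tested probes, with probes per bin on a log axis (vertical), called probes outlined and other probes filled; differences are as fitted, with no lower bounds. The called probes extend on both sides, 7842 higher and 7468 lower in MCF-7/ADM.

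The probes with the largest increases among those measurable on all 6 arrays belonged to the custom family. CUST_8657_PI429545388 (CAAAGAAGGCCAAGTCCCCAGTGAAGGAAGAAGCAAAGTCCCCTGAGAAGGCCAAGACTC) rose from a log2 level of -1.56 ± 0.15 to 7.47 ± 0.08 relative to the 75th percentile of the array (SD, n = 3 per line). That is an increase of 9.03 log2 units (SE 0.10), or 521-fold, with adjusted p = 1.82e-07 by limma with Benjamini-Hochberg adjustment. CUST_71837_PI429545399 (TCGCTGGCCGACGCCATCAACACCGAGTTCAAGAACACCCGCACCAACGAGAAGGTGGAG) rose from -2.02 ± 0.16 to 6.12 ± 0.11 (SD, n = 3 per line). Its increase was 8.14 log2 units (SE 0.11), or 282-fold, at a limma Benjamini-Hochberg adjusted p of 2.14e-07.

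The probes with the largest decreases among those measurable on all 6 arrays were also custom. CUST_27383_PI429545402 (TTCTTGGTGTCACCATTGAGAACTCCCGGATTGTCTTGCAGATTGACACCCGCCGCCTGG) went from 5.66 ± 0.10 in MCF-7 to -1.58 ± 0.07 in MCF-7/ADM (SD, n = 3 per line). It fell by 7.24 log2 units (SE 0.09), to a level 152-fold lower, at a limma Benjamini-Hochberg adjusted p of 1.82e-07. CUST_9244_PI429545388 (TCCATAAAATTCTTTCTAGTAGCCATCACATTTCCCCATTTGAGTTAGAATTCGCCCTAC) went from 5.13 ± 0.22 to -1.82 ± 0.43 (SD, n = 3 per line). It fell by 6.94 log2 units (SE 0.23), to a level 123-fold lower, at a limma Benjamini-Hochberg adjusted p of 3.02e-06. The files pair these probes with neither a gene nor a position, so their transcripts are not named here.

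PGK1, the glycolytic enzyme phosphoglycerate kinase, was lower in MCF-7/ADM by both of its control probes. The probe toward the 3' end of its transcript fell by 0.52 log2 units (SE 0.09) and the one toward the 5' end fell by 0.60 (SE 0.10), with limma Benjamini-Hochberg adjusted p = 0.00224 and 0.00283. All 3 MCF-7/ADM arrays lay below all 3 MCF-7 arrays for both probes. Both stayed under the 2-fold threshold and were not called. With the slide as a block, which rests on MCF-7/ADM replicate 1, the values were -0.41 and -0.44, with limma Benjamini-Hochberg adjusted p = 0.0144 and 0.0192. GAPDH, glyceraldehyde-3-phosphate dehydrogenase of the same pathway, gave -0.06 (SE 0.09) and -0.08 (SE 0.08) at its 3' and 5' probes, with limma Benjamini-Hochberg adjusted p = 0.569 and 0.448. Its sign turned at the 3' probe under median centring (0.0059) and at the 5' probe under quantile normalisation (0.0067).

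The gap between 3' and 5' probes, a sign of RNA integrity, was close in the lines. It was 0.79 ± 0.03 log2 units in MCF-7/ADM and 0.77 ± 0.05 in MCF-7 for GAPDH, and 2.92 ± 0.04 and 2.84 ± 0.09 for PGK1 (SD, n = 3 per line).

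**Figure D3:**
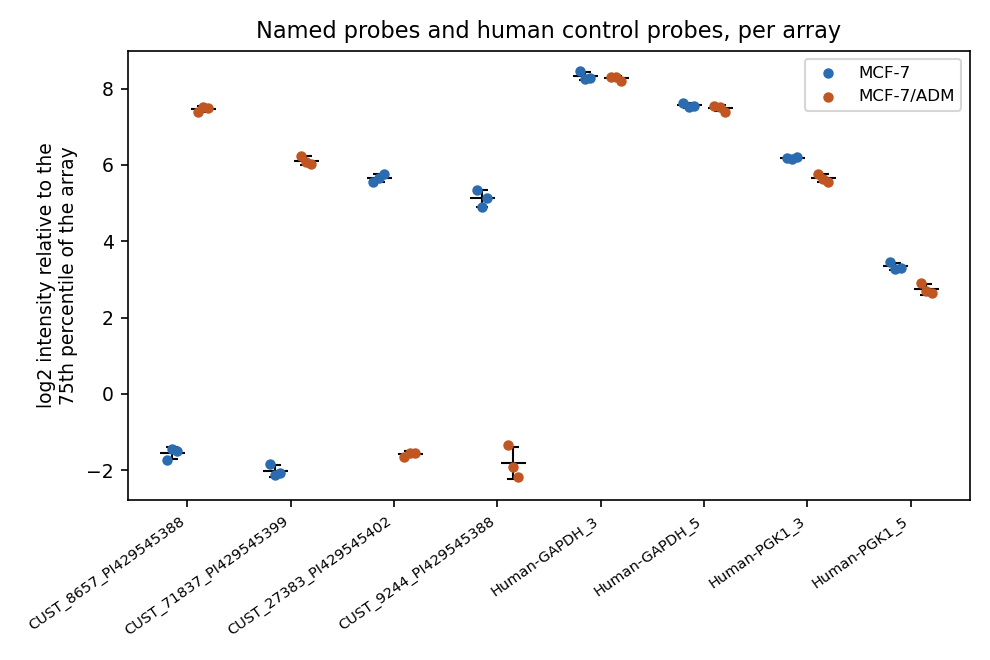
Log2 intensity relative to the 75th percentile of each array (vertical) for the 4 named probes and the 4 human control probes (horizontal), with a point per array and the mean and SD of each line as bars. CUST_8657_PI429545388 stands at 7.47 in MCF-7/ADM and -1.56 in MCF-7, while PGK1 differs by -0.52 and -0.60.

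Some RNAs were measurable in only 1 line. On all 3 MCF-7/ADM arrays and no MCF-7 array, 3259 probes were well above background, 1354 of them catalogue and 1905 custom. Of these, 880 were at least 8-fold and 236 at least 32-fold higher by the lower bound, and 2688 were called. On all 3 MCF-7 arrays and no MCF-7/ADM array there were 694 such probes, 490 of them at least 8-fold and 147 at least 32-fold higher in MCF-7 by the bound, and 676 were called. The bounds are not comparable between the lines, since the lowest signal well above background was lower on the second slide. The excess in MCF-7/ADM did not hold within the first slide. There, 4882 to 5755 probes were above background in MCF-7/ADM replicate 1 only, and 6601 to 8776 in the MCF-7 array only, depending on the MCF-7 array. Against the arrays of the second slide the counts were 18348 to 20947 and 1311 to 1896.

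Catalogue probes differed between the lines more often than custom probes. Of 21739 catalogue probes tested, 6691 (30.8%) were called, 3498 higher and 3193 lower in MCF-7/ADM. Of 34156 custom probes tested, 8619 (25.2%) were called, 4344 higher and 4275 lower. The difference of 5.54 percentage points had a 95% interval of 4.78 to 6.31 (Fisher's exact test, two-sided, p = 3.36e-46, across probes). More of the catalogue family passed the filter: 66.3% of its probes were tested, against 43.7% of the custom family. Most catalogue probes had 2 spots, of which 1 above background was enough, while most custom probes had 1 spot. The filter was thus easier to pass for catalogue probes. With no filter the difference was 8.89 points, so the gap did not need the filter, though undetected probes of both families then enter. Among probes well above background on all 6 arrays, the main fit called 22.8% of catalogue and 17.5% of custom probes. That is a difference of 5.32 points (95% interval 4.56 to 6.08), under the same rule for spots.

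Probes lying on opposite strands of the same sequence changed together. Reverse-complement probes overlapping at their ends by at least 20 nt formed 263 pairs, of which 133 had both probes tested. Pairs overlapping only at their starts were not searched for. Their log2 changes correlated across pairs at Pearson's r = 0.679 and Spearman's rho = 0.648, each with a permutation p of 1e-05, the smallest the permutations can give. Without the 2 pairs farthest from the median, r was 0.641. Both probes moved the same way in 96 pairs (72.2%, against 50.7% by chance). Where both probes were called, 20 of 21 pairs went in the same direction, and in 28 pairs only 1 probe was called.

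Same-strand probes gave a reference for how closely probes of shared sequence follow each other. Of 6529 such pairs, 3506 had both probes tested, and r was 0.938. Of the 919 same-strand pairs with both probes called, 918 went in the same direction. The median difference of log2 change within a pair was 0.34 for reverse-complement and 0.12 for same-strand pairs. Pairs are not independent replicates, since a probe can lie in several.

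**Figure D4:**
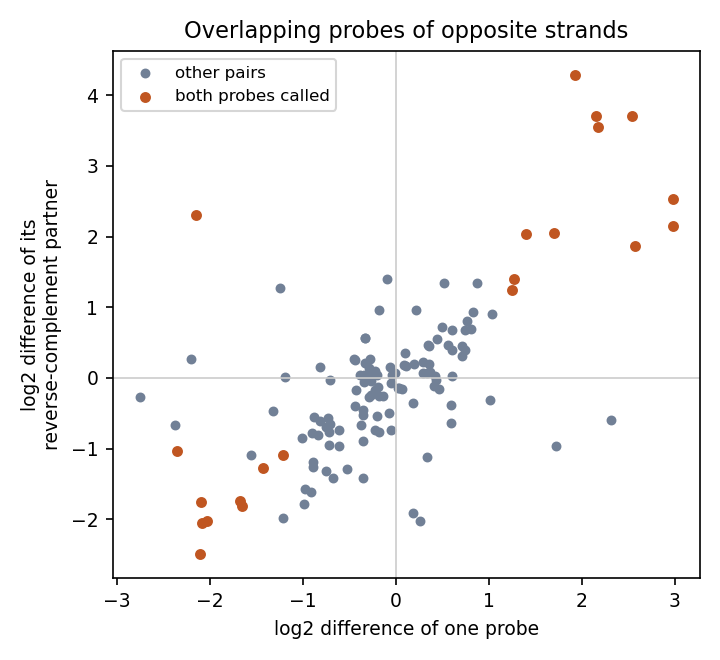
Log2 difference between MCF-7/ADM and MCF-7 of each probe (horizontal) and of its reverse-complement partner (vertical) for 133 pairs, with pairs in which both probes were called in orange. The pairs lie along the diagonal with r = 0.679, and 20 of the 21 pairs with both probes called go in the same direction.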

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

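Signal of a control probe for a mouse transcript, which no comparison above uses, was looked at because its mean was higher in MCF-7/ADM than in MCF-7. Mouse-PGK1_3 gave a difference of 0.76 log2 units, at -3.95 against -4.71 relative to the 75th percentile. On the first slide its values were at most -4.58, below the lowest signal of any probe well above background there (-3.92 to -3.53), so this difference is no measured change between the lines. The arrays of the second slide, at -3.51 and -3.77, carried most of it. Other control probes parted the arrays of the lines in the opposite direction, among them Rat-PGK1_5 at -0.59 and Mouse-PGK1_5 at -0.56. ERCC-00028_121 differed by -0.81, with the arrays of the second slide at -2.30 and -2.43 and MCF-7/ADM replicate 1 at -1.64, against a lowest MCF-7 array of -1.39. Mouse-GAPDH_3 differed by -0.65, but most of it lay on the second slide, at -0.68 and -0.44, while MCF-7/ADM replicate 1 lay at 0.13 and the lowest MCF-7 array at 0.18. ERCC-00097_63 was also lower in MCF-7/ADM, but on replicate 1, at -3.74, it lay below the lowest signal well above background on that array (-3.53), so no exact difference is given. None of these differences was tested.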

How the results depend on the processing

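The comparison within the first slide and all alternatives for families, pairs and control probes were chosen after seeing the data. Of 15310 called probes (7842 higher, 7468 lower), no alternative called any in the opposite direction. Counts moved by over 1.5 times under normexp (8083; 4377 and 3706), in a fit of only the probes above background on all 6 arrays (8940; 4317 and 4623), with no minimum fold (33976; 15330 and 18646), at 4-fold as fitted (6085; 3509 and 2576) and with treat (9498; 5082 and 4416). The stricter filter tests fewer probes and the fold rules differ by construction. Under normexp the SD of the log2 changes over the tested probes was 0.84, against 1.43 in the main fit. Limma gave an unadjusted p under 0.05 for 36260 probes there, against 36395. The normexp calls were thus lost at the fold threshold, through smaller changes. Quantile normalisation without normexp gave an SD of 1.45 and 15321 called probes, which argues against the quantile step as the source. Which of the remaining steps made the changes smaller was not tested. The difference between families was 4.38 points under normexp, 8.89 with no filter, 8.50 with no minimum fold and 3.22 at 4-fold, and the cause was not tested. For reverse-complement pairs, r was 0.512 over 263 pairs with no filter and 0.620 under normexp. It was 0.803 over 78 pairs overlapping by at least 40 nt and 0.825 over the 21 pairs with both probes called.

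Leaving out an array gave 14954 to 16325 called probes (7675 to 8285 higher, 7237 to 8040 lower), 4.49 to 5.82 points between families and r = 0.637 to 0.696 for reverse-complement pairs. The named probes ranged from 8.94 to 9.09, 8.08 to 8.23, -7.29 to -7.20 and -7.18 to -6.76. PGK1 ranged from -0.58 to -0.47 and from -0.68 to -0.55, GAPDH from -0.10 to -0.00065 and from -0.11 to -0.03. GAPDH turned to 0.0059 at its 3' probe under median centring and 0.0067 at its 5' probe under quantile normalisation, with no call in any setting.

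The replicate numbers did not mark a pairing: deviations of same-numbered arrays correlated at -0.04, -0.0025 and -0.09. With the number as a block, 15204 probes were called. The named probes kept their calls and direction in every setting run for them. Both PGK1 probes kept their direction and an adjusted p under 0.05, and stayed under 2-fold. Alternatives set out for genes, lists, ABCB1, antisense pairs and neighbours were not run, since the files name no genes. Signal over background limits dim probes: with no filter, 18251 were called.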

Other observations

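The tests on other splits of the arrays, on RNA degradation and on hybridisation differences between slides were chosen only after related results had been seen. The split of called probes by direction is given here by brightness, without a test. In the dimmest of 5 equal groups by mean signal, 1216 catalogue probes were higher and 901 lower in MCF-7/ADM, and custom probes split 1489 and 1448. In the brightest group, 341 catalogue probes were higher and 512 lower, and custom probes split 408 and 554. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave 15310 called probes with limma. The highest other gave 0, but 10 splits are too few for a share under 0.05. Each other split mixes the lines, so the difference between the lines enters its residual spread and calls were unlikely from the start. The 0 is thus no measure of calls by chance.

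MCF-7/ADM replicate 1 stood apart from replicates 2 and 3 by at least 2-fold for 1762 of 45411 probes, 1341 lower and 421 higher. A lower background on the second slide would spare bright probes, yet 4.92% of the brightest of 3 groups showed such a gap against at most 0.383% between MCF-7 arrays, and RNA degradation is argued against by 3' minus 5' gaps of only -0.0614 (PGK1) and -0.0331 (GAPDH) log2 units between them, within the range among MCF-7 arrays. Mixed-in MCF-7 RNA would move probes toward MCF-7, and only 4.99% of these probes deviated away from it, but a shared slide would do the same, and the 501 probes at least 32-fold higher in MCF-7 allow a share of 3.63%, where the lower probes need 61.6% and the higher ones 131.5%. Hybridisation that differs by probe between the slides may account for it, as 93.5% of these probes lay nearer to MCF-7, which shares the slide. That stays open together with an untested difference between cultures, since 25 spike-in and deletion control probes were split: their median gap was 0.13 log2 units across slides and 0.19 against MCF-7 on the same slide, but 10 lay farther across slides, with DCP_1_7 at -0.91 against -0.10.

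Reverse-complement probes changed together (r = 0.679). If both probes read a single RNA, they would follow each other as same-strand pairs do. Among pairs with at least 1 called probe, their difference was instead 4.08 times that of same-strand pairs (0.76 against 0.19). These sets were not matched for overlap length, and r was 0.803 in the 78 reverse-complement pairs overlapping by at least 40 nt. A partial contribution across strands stays open. A shared background shift of dim probes is argued against by r = 0.859 in the 43 pairs with both probes above the median signal of the tested probes (permutation p = 1e-05, the smallest the permutations can give). Joint regulation of overlapping transcripts may contribute, as a hypothesis, and was not tested.

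Catalogue probes were called more often than custom probes. More spots per catalogue probe would make the families alike among probes spotted 10 times, but there the difference was 13.7 points (95% interval 9.72 to 17.7). Those probes may not stand for their families: 16.7% of the custom ones were called, against 25.2% of all custom probes tested. The gap among them therefore cannot exclude spot number as a cause of the gap between the whole families. Brighter catalogue probes would make them alike within groups of equal signal, but the weighted difference over 5 such groups was 5.92 points (5.17 to 6.67). From the dimmest to the brightest group, the share called fell from 49.7% to 18.6% for catalogue and from 42.5% to 14.6% for custom probes. The groups rest on mean signal over both lines, so a probe near background in only a single line is moved toward the dimmer groups by its own difference. Such called probes numbered 2688 higher and 676 lower in MCF-7/ADM, above background on no array of the other line. The fall in calls with signal can thus be partly built in. It therefore cannot decide whether brightness is a source of the higher catalogue share. What the families target is not given in the files, so no biological explanation was tested.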
